A study of Homo sapiens with 6 samples.

How the data were processed

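RNA-seq was made from CWR-R1 cells, an established human castration-resistant prostate cancer cell line, as 3 Control libraries, which the sample titles call untreated, and 3 libraries of a SOX2 knockout, named SOX2-KO here. Groups and replicate numbers were taken from the sample titles, and all 6 columns of the deposited table matched 1 sample each. How the knockout was made, whether it is a single clone, and whether the replicates were separate cultures are not given in the sources used here.

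The authors deposited 1 table of CPM values for 16949 Ensembl gene identifiers. Each deposited CPM column added up to 1000000 over the listed genes, so the authors' values were scaled by library total and by nothing else that the table shows. The submitters' processing notes name FastQC, STAR, SAMtools, Picard, CASAVA 1.8, Trimmomatic 0.38, kallisto 0.43.1 and edgeR 3.22.2 and the builds GRCh38.p12 and hg38, with no role or order for any of them. How genes were selected for the table, and whether counting used the strand, are not given in the sources used here.

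In every column part of the values were whole multiples of a fixed step, taken as the value of 1 read. The step was sought only within a set range, and the read totals rest on it. These were 21846204, 25323865 and 20717788 estimated reads for Control replicates 1, 2 and 3, and 21948972, 22069378 and 25739759 for SOX2-KO replicates 1, 2 and 3. From 26.6% to 28.4% of the values per library were whole numbers of reads within 0.001 of a read, against 0.2% by chance. The remaining values were fractional, as estimates that divide reads between transcripts are, so whole reads were not recovered and no count model was used. A floor of 3 reads corresponded to 0.117 to 0.145 CPM per library, which covers counting error only. Gene names, types and GRCh38 coordinates came from GENCODE 29, which held 16010 of the identifiers. The other 939 identifiers, with 2.02% to 2.17% of the CPM of a library, were tested without coordinates. For 664 genes the 6 values were identical to those of another gene, so that such genes are not separate measurements.

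The design chosen before the data were examined used a count model if the table held counts and limma if it held normalised values. Since the table held CPM, limma 3.58.1 in R 4.3.3 was applied to log2(CPM + 1) with a trended variance prior, for the 15927 genes with a mean of at least 1 CPM over the 6 libraries, with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower, and every adjusted p of a gene comes from this test unless another is named. Log2 fold changes are on the log2(CPM + 1) scale, which understates the change of low genes, while folds of named genes are ratios of mean CPM. Counts of genes by fold, and the test against a minimum fold, use the log2(CPM + 1) scale. SOX2 was also compared by an exact two-sided permutation test. For 36 gene lists, written before the data were examined, the 33 with at least 5 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Camera was repeated with a correlation estimated from each list, and fry was run on each list by itself. Members called in each direction were counted over all genes tested and again adjusted over the list alone.

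The genes named in the text follow a rule set beforehand: SOX2; the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between the groups; and, from each list, up to 2 members with the smallest p among those that rose, up to 2 among those that fell, and up to 2 of the highest mean among those not called. Genes named outside the rule are given as such. The per-gene test was tried on data simulated for SOX2-KO against Control, with 15627 genes tested, 200 of which were changed by set folds and 20 more as a list. Of the genes changed 1.25-fold 84% were recovered, and 100% of those changed 1.5-fold, 2-fold or 4-fold. There were 13 unchanged genes called (0.08% of them, and 5.94% of the 219 genes called). The simulated genes were independent, shared 1 dispersion and were mostly unchanged, unlike the data. The simulation therefore does not check camera's preset correlation or a count of calls as large as that found. Replicates of a group differed by more than counting noise in every pair, with a median chi-square per gene of 0.849 to 1.84 against 0.455 expected from counting, so each library was used as 1 replicate.

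Alternatives listed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter of at least 5 CPM, median-ratio scaling, quantile normalisation, the replicate number as a block, a test against a minimum fold of 1.5, the estimated correlation, fry, and leaving out each library in turn. Alternatives added after seeing the data were limma-voom on estimated reads, GENCODE 29 genes only, the table without mitochondrially encoded genes and ribosomal RNA loci, and subtraction of the median log2 fold change of the 100 nearest tested genes on the chromosome, called the chromosomal neighbourhood here. The subtracted median came from the same fold changes and was treated as known without error. Every p after this subtraction, of genes and of lists, leaves that error out and is too small. Positional tests used 10000 permutations in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with log2 fold changes limited to ±1. Y-linked genes were left out of the text, and some genes that the rule names are not reported here.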

Results

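The transcriptome of CWR-R1 prostate cancer cells was compared between SOX2 knockout and control cells, to ask which genes, those of metabolism above all, change when this stem cell transcription factor is missing. CWR-R1 is a castration-resistant line derived from a human prostate cancer xenograft. There were 3 libraries per group, and values below are mean CPM ± SD with n = 3 in each group unless another n is given. The estimated reads on the listed genes were 20717788 to 25739759 per library, and the median standard error of a log2 fold change was 0.0788. Reads outside the listed genes are not known. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

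SOX2 mRNA fell in all 3 SOX2-KO libraries. Its level went from 55.1 ± 0.771 to 4.36 ± 0.467 CPM, so that 7.91% of the Control level was left (log2 fold change −3.39 ± 0.08, standard error; limma adjusted p = 1.65e-08). No SOX2-KO value overlapped a Control value. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. SOX2 (ENSG00000181449) is a gene on chromosome 3, positions 181711924 to 181714436 of GRCh38, on the plus strand.

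The genes with the largest changes included genes of the extracellular matrix, metal reduction, cell surface signalling and amine metabolism. TNC, which encodes the matrix glycoprotein tenascin C, rose 112-fold, from 0.752 ± 0.0974 to 84.1 ± 5.55 CPM (log2 5.60, adjusted p = 2.15e-09). The metalloreductase gene STEAP2 and the adjacent gene STEAP1 on chromosome 7 rose 31.4-fold and 42.1-fold, from 3.56 ± 0.535 to 112 ± 4.197 CPM and from 0.906 ± 0.349 to 38.1 ± 2.21 CPM. EPHB3, an ephrin receptor tyrosine kinase gene, fell 66.5-fold, from 81.1 ± 3.69 to 1.22 ± 0.249 CPM (log2 −5.21, adjusted p = 7.84e-09). MAOA, the monoamine oxidase A gene, fell 12.9-fold, from 224 ± 4.66 to 17.3 ± 0.157 CPM (log2 −3.62, adjusted p = 4.55e-10). On GRCh38, TNC (ENSG00000041982) is a gene on chromosome 9, positions 115019578 to 115118257, and STEAP1 (ENSG00000164647) and STEAP2 (ENSG00000157214) start at 90154375 and 90167590 on chromosome 7. EPHB3 (ENSG00000182580) is on chromosome 3, positions 184561784 to 184582409, beyond SOX2, and MAOA (ENSG00000189221) on chromosome X, positions 43654907 to 43746824.

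Among the other genes with the largest rises, the atypical chemokine receptor gene ACKR3 rose from 5.104 ± 0.203 to 49.97 ± 1.498 CPM, the WNT receptor gene FZD4 from 10.2 ± 0.594 to 77.3 ± 3.66 CPM and the chemokine gene CX3CL1 from 30.6 ± 2.03 to 214 ± 7.46 CPM. The zinc finger gene ZNF729 rose from 0.966 ± 0.318 to 14.3 ± 0.457 CPM. AC120057.2 was called higher, from 3.35 ± 3.14 to 27.5 ± 10.4 CPM, but 89% of its exonic bases are also exonic in GABARAP, so its estimate is uncertain. Among the other largest falls, the melanophilin gene MLPH fell from 168 ± 7.26 to 6.05 ± 1.12 CPM, TMTC1 from 121 ± 0.479 to 4.38 ± 0.213 CPM and the plakophilin gene PKP1, a desmosome component, from 41.99 ± 2.29 to 2.37 ± 0.424 CPM. ARMCX3 fell from 13.9 ± 1.08 to 0.231 ± 0.076 CPM and IGFBPL1 from 13.6 ± 0.405 to 0.283 ± 0.0617 CPM. The SOX2-KO levels of these last genes lie close to the floor of 0.117 to 0.145 CPM per library.

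**Figure D1:**
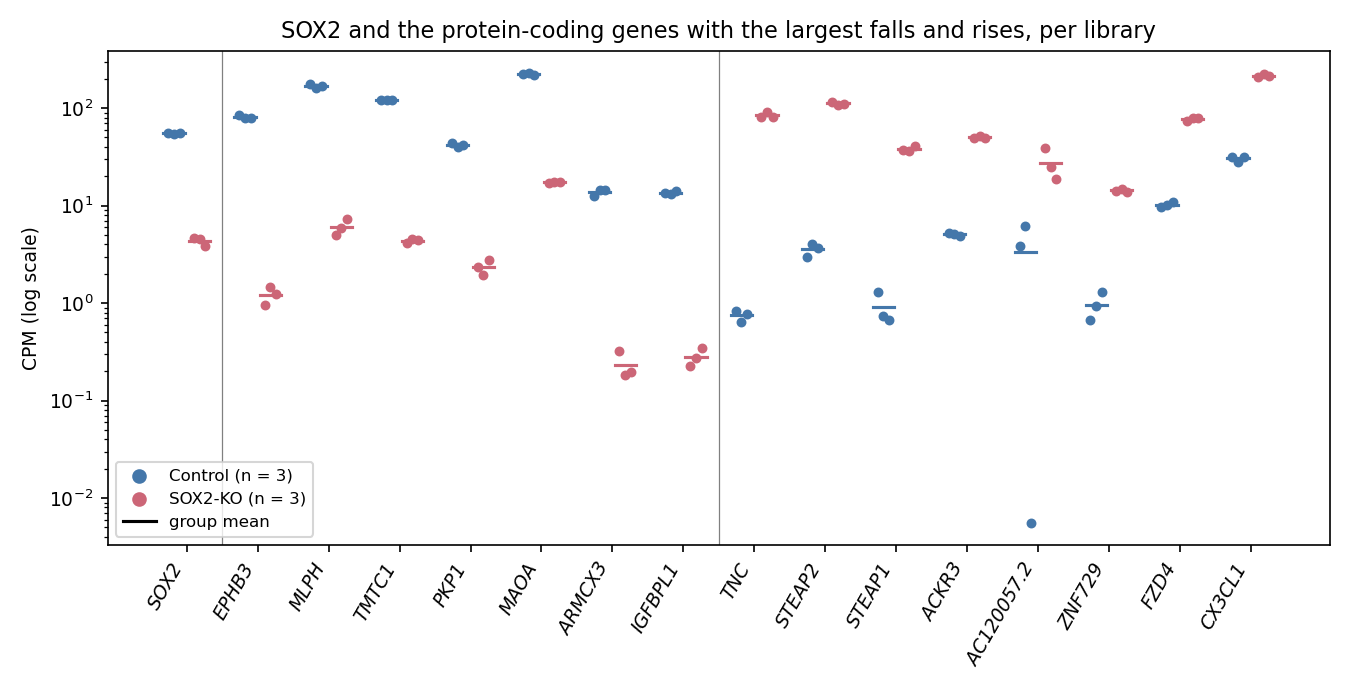
CPM on a log axis of SOX2, the other 7 protein-coding genes with the largest falls and the 8 with the largest rises, with 1 point per library and a bar at the group mean, for Control (blue, n = 3) and SOX2-KO (red, n = 3). SOX2 lies near 55.1 CPM in Control and 4.36 CPM in SOX2-KO, and the groups do not overlap for any gene shown, although AC120057.2 spreads widely between replicates.

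Of 15927 genes tested, 9210 (57.8%) were called, 3976 higher and 5234 lower in SOX2-KO, a balance that turned with median-ratio scaling (4579 higher, 4522 lower), quantile normalisation (4670 higher, 4498 lower) and the neighbourhood subtraction (4431 higher, 4168 lower). Most of the changes were small on the log2(CPM + 1) scale. By that scale 67.8% of the called genes changed by less than 1.5-fold, and 311 were at least 2-fold higher and 525 at least 2-fold lower. Some low genes outside these 2-fold counts changed more than 2-fold in mean CPM, such as VIM (2.22-fold lower, log2 −0.81). In 64.5% of the tested genes the 3 values of one group did not overlap those of the other, against 10% by chance. Tested against a minimum fold of 1.5 on the log2(CPM + 1) scale, 1042 genes were called, 393 higher and 649 lower.

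Most of the glycolytic enzyme genes tested rose. Of 17 genes tested, 14 rose and 3 fell, with the same counts adjusted over the list alone. The phosphofructokinase gene PFKM rose from 147 ± 2.94 to 256 ± 2.03 CPM (adjusted p = 4.64e-07) and the lactate dehydrogenase gene LDHB from 709 ± 9.22 to 1027 ± 13.7 CPM (adjusted p = 6.07e-06). LDHA, named after its value was seen, rose from 271 ± 13.4 to 509 ± 72.6 CPM (adjusted p = 3.53e-05). HK1, a hexokinase gene for the entry step, fell from 134 ± 2.86 to 89.9 ± 4.92 CPM (adjusted p = 1.41e-05), and PFKP fell from 1.998 ± 0.611 to 0.19 ± 0.078 CPM, close to the floor in SOX2-KO. The list stood above other genes by camera (adjusted p = 0.00318, median log2 0.40), but not when the correlation was estimated (adjusted p = 0.588 with an estimated correlation).

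Genes of glucose and lactate transport and of glycolytic control went both ways, and hypoxia-inducible genes fell more often than they rose. Of 22 transport and control genes tested, 9 rose and 10 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.889; median log2 −0.08, while camera's direction was higher). PDK4, an inhibitory kinase of pyruvate dehydrogenase, rose from 371 ± 13.5 to 653 ± 15.1 CPM, and TXNIP, a negative regulator of glucose uptake, from 66.4 ± 10.1 to 114 ± 4.33 CPM. The inositol transporter gene SLC2A13 fell from 36.3 ± 2.74 to 14.2 ± 1.31 CPM and PFKFB3, which makes an activator of phosphofructokinase, from 523 ± 12.8 to 349.8 ± 8.38 CPM. The monocarboxylate transporter gene SLC16A1 was not called (62.3 ± 3.62 to 62.1 ± 4.44 CPM). Of 23 hypoxia-inducible genes tested, 5 rose and 13 fell, the same adjusted over the list alone, among them ANGPTL4, which fell from 48.3 ± 1.46 to 21.7 ± 0.47 CPM. The mitophagy gene BNIP3L rose from 62.8 ± 4.33 to 103 ± 3.05 CPM. The hypoxia list as a whole was not called (camera adjusted p = 0.159, median log2 −0.37).

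Of 23 genes of pyruvate dehydrogenase and the TCA cycle, 13 rose and 5 fell, and 14 rose and 5 fell adjusted over the list alone. DLD, the dihydrolipoamide dehydrogenase shared by several mitochondrial complexes, rose from 109 ± 4.04 to 247 ± 2.59 CPM (adjusted p = 1.17e-07), and PDHA1 from 94.8 ± 0.643 to 128 ± 1.247 CPM. The isocitrate dehydrogenase gene IDH2 fell from 150.2 ± 6.86 to 82.1 ± 1.95 CPM (adjusted p = 1.11e-06), and SUCLG1 was not called (106 ± 2.102 to 101 ± 2.84 CPM). The list was called higher by camera (adjusted p = 0.0441) but not with the other correlation (adjusted p = 0.608 with an estimated correlation), and the call ended without Control replicate 3 (0.0643), without SOX2-KO replicate 1 (0.081), with the replicate number as a block (0.056), with quantile normalisation (0.0683) and with at least 5 CPM (0.0515; adjusted p from 0.0121 to 0.081 over the alternatives that keep camera and its preset correlation).

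Nuclear genes of the respiratory chain rose more often than they fell, without a call for any of these lists. Of 37 complex I genes, 14 rose and 9 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.211). NDUFV2 rose from 81.3 ± 1.85 to 153 ± 6.64 CPM and NDUFS6 fell from 63.5 ± 0.996 to 44.02 ± 2.59 CPM. Of 21 genes of complexes III and IV, 11 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.0555). NDUFA4 rose from 101 ± 4.15 to 154 ± 1.35 CPM, and COX5A fell from 120.3 ± 4.39 to 87.6 ± 4.103 CPM. COX6A1 fell from 297 ± 8.205 to 245 ± 7.95 CPM, a call that ended, with the sign turned, when the chromosomal neighbourhood was subtracted (log2 0.03, adjusted p = 0.559; adjusted p from 2.18e-04 to 0.559 over the alternatives). This list was called without SOX2-KO replicate 3 (adjusted p = 0.0333), with median-ratio scaling (0.0466), with limma-voom (0.042), with no filter (0.0497) and with the neighbourhood subtracted (0.0193; adjusted p from 0.0193 to 0.0826 over the alternatives that keep camera and its preset correlation; adjusted p = 0.497 with an estimated correlation). Of 16 ATP synthase genes, 7 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.152; 0.0288 with the neighbourhood subtracted; adjusted p from 0.0288 to 0.193 over the alternatives that keep camera and its preset correlation; adjusted p = 0.608 with an estimated correlation). ATP5F1A, the alpha subunit, rose from 562 ± 2.61 to 824 ± 27.1 CPM. ATP5F1D, the delta subunit, fell from 121 ± 8.903 to 101 ± 2.95 CPM, a call that ended, with the sign turned, with the neighbourhood subtracted (adjusted p = 0.591; adjusted p from 0.00152 to 0.591 over the alternatives).

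Transcripts encoded by mitochondrial DNA differed between the SOX2-KO libraries. They made up 2.70%, 2.46% and 2.51% of the reads on the listed genes in Control replicates 1, 2 and 3, and 1.35%, 1.30% and 2.74% in SOX2-KO replicates 1, 2 and 3. Exact 95% binomial intervals, which cover counting error only, ran for example from 2.692% to 2.705% in Control replicate 1 and from 2.73% to 2.743% in SOX2-KO replicate 3. Of 12 transcripts tested, 0 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.276; 7.37e-05 without SOX2-KO replicate 3; adjusted p from 7.37e-05 to 0.505 over the alternatives that keep camera and its preset correlation; adjusted p = 0.843 with an estimated correlation). MT-ND1 fell from 1439.8 ± 89.8 to 744 ± 330.4 CPM (adjusted p = 0.0048) and MT-CO3 from 2165 ± 85.5 to 1214 ± 519 CPM. MT-ND4 (4275 ± 253 to 3444 ± 1629 CPM) and MT-CO2 (2918 ± 139 to 2202 ± 1042 CPM) were not called unless SOX2-KO replicate 3 was left out (adjusted p = 2.91e-05 and 9.73e-06) or, for MT-CO2, with quantile normalisation (0.0287). Of 17 genes of mitochondrial biogenesis and DNA maintenance, 2 rose and 6 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.808). The helicase gene TWNK rose from 33.6 ± 3.19 to 50.3 ± 2.21 CPM and the coactivator gene PPARGC1B fell from 65.6 ± 3.05 to 41.8 ± 3.45 CPM.

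Most of the tested genes of fatty acid oxidation and of cholesterol synthesis and uptake rose. Of 24 fatty acid oxidation genes, 16 rose and 7 fell, the same adjusted over the list alone, and the list was called by camera (adjusted p = 0.0107, median log2 0.38; adjusted p = 0.468 with an estimated correlation). ECHS1, which encodes an enoyl-CoA hydratase, rose from 103 ± 4.205 to 223 ± 7.83 CPM (adjusted p = 3.05e-07) and the trifunctional protein gene HADHA from 199 ± 1.29 to 352 ± 5.55 CPM. CPT1A, the entry enzyme in most tissues, fell from 166 ± 1.35 to 128 ± 9.35 CPM. Of 24 genes of cholesterol synthesis and uptake, 15 rose and 2 fell (16 and 2 adjusted over the list alone), and this list was called too (adjusted p = 0.00229, median log2 0.27; adjusted p = 0.578 with an estimated correlation). MSMO1 rose from 23.1 ± 0.54 to 42.2 ± 2.74 CPM and FDFT1, the squalene synthase gene, from 92.4 ± 6.001 to 152 ± 7.18 CPM. SQLE, the squalene epoxidase gene, fell from 16.6 ± 0.216 to 11.7 ± 1.62 CPM and TM7SF2 from 55.05 ± 4.98 to 31.3 ± 1.04 CPM.

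Of 16 genes of fatty acid synthesis and desaturation, 10 rose and 4 fell, the same adjusted over the list alone. The elongase gene ELOVL5 rose from 171 ± 5.12 to 365 ± 12.7 CPM (adjusted p = 2.31e-07), and ACSS2, which makes acetyl-CoA from acetate, from 86.9 ± 2.98 to 200.4 ± 10.3 CPM. The desaturase gene SCD5 fell from 22.5 ± 1.33 to 11.7 ± 1.03 CPM and ACACB from 30.01 ± 0.87 to 19.5 ± 0.992 CPM. Camera called the list at adjusted p = 0.0441 (adjusted p = 0.468 with an estimated correlation), and the call ended without Control replicate 1 (adjusted p = 0.0559), Control replicate 2 (0.0516), Control replicate 3 (0.0553) or SOX2-KO replicate 1 (0.058), with the replicate number as a block (0.056), with median-ratio scaling (0.0517), with quantile normalisation (0.0683) and with the neighbourhood subtracted (0.0691; adjusted p from 0.0208 to 0.0691 over the alternatives that keep camera and its preset correlation).

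Of 9 pentose phosphate pathway genes, 6 rose and 1 fell, the same adjusted over the list alone. PGD rose from 139 ± 4.88 to 244 ± 10.5 CPM and the transketolase gene TKT from 217 ± 11.98 to 347 ± 17.4 CPM. PGLS fell from 38.5 ± 2.83 to 28.8 ± 3.36 CPM, a call that ended with the neighbourhood subtracted (adjusted p = 0.216; adjusted p from 0.00236 to 0.216 over the alternatives). The list gave a camera adjusted p = 0.0638, and 0.0464 with limma-voom (adjusted p from 0.0464 to 0.169 over the alternatives that keep camera and its preset correlation; adjusted p = 0.468 with an estimated correlation). Of 15 genes of serine, glycine and folate metabolism, 7 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.175). PSPH, the last enzyme of serine synthesis, rose from 87.4 ± 1.19 to 127 ± 3.402 CPM and the mitochondrial folate enzyme gene ALDH1L2 fell from 478 ± 5.54 to 338 ± 13.9 CPM. Of 16 genes of glutamine and amino acid supply, 9 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.331). The asparagine synthetase gene ASNS rose from 343 ± 8.15 to 675 ± 64.04 CPM. SLC7A5, a transporter of large neutral amino acids, fell from 1708 ± 88.9 to 934 ± 46.98 CPM, and GOT1 from 209 ± 3.04 to 109.7 ± 11.3 CPM.

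Most of the androgen response genes tested rose, among them STEAP2. Of 25 tested, 15 rose and 4 fell (15 and 5 adjusted over the list alone), and camera called the list (adjusted p = 0.0112, median log2 0.47; adjusted p = 0.468 with an estimated correlation). KLK3, the gene of prostate-specific antigen, and FKBP5 rose from 2.82 ± 0.13 to 8.95 ± 1.22 CPM and from 1262 ± 38.5 to 1791 ± 54.4 CPM; both are named after their values were seen. The transporter gene ABCC4 fell from 109 ± 1.24 to 30.5 ± 2.42 CPM (adjusted p = 1.13e-07), and MPHOSPH9 from 170.4 ± 5.89 to 93.8 ± 5.09 CPM.

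Lineage and stem cell markers moved in both directions. Of 11 prostate luminal markers, 6 rose and 3 fell (camera adjusted p = 0.0695). The transcription factor gene GATA2 rose from 150.4 ± 8.82 to 359 ± 7.25 CPM, the E-cadherin gene CDH1 fell from 694 ± 13.3 to 589 ± 26.3 CPM and FOXA1 was not called (385 ± 10.4 to 372 ± 8.498 CPM). Of 7 prostate basal markers, 1 rose and 4 fell (camera adjusted p = 0.141): EGFR rose from 25.2 ± 2.11 to 50.2 ± 5.88 CPM and JAG1 fell from 26.4 ± 1.03 to 14.3 ± 1.03 CPM. Of 7 neuroendocrine markers, 1 rose and 4 fell (camera adjusted p = 0.358): ENO2, which is also a glycolytic enzyme gene, rose from 462 ± 20.7 to 676 ± 21.6 CPM, and the secretogranin gene SCG2 fell from 12.3 ± 0.314 to 4.93 ± 0.485 CPM. Of 10 pluripotency and stem cell genes, which leave SOX2 itself out, 1 rose and 6 fell (camera adjusted p = 0.0638; 0.0477 with median-ratio scaling, 0.0142 with at least 5 CPM and 0.049 with no filter; adjusted p from 0.0142 to 0.0826 over the alternatives that keep camera and its preset correlation; adjusted p = 0.468 with an estimated correlation). ALDH1A1, the retinaldehyde dehydrogenase used as a stem cell marker, fell 7.98-fold, from 194 ± 2.496 to 24.3 ± 0.471 CPM (adjusted p = 7.71e-10), NES fell from 93.02 ± 5.197 to 53.9 ± 4.36 CPM and SALL2 rose from 2.07 ± 0.327 to 5.32 ± 1.55 CPM. Of 11 other SOX genes, 3 rose and 5 fell (camera adjusted p = 0.379). SOX9 rose from 7.62 ± 0.611 to 12.3 ± 1.28 CPM and SOX12 fell from 99.8 ± 5.81 to 48.3 ± 1.43 CPM. For these lists, the counts adjusted over the list alone were the same.

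Most of the ribosomal protein genes tested rose. Of 47 cytosolic ribosomal protein genes, 31 rose and 4 fell (32 and 4 adjusted over the list alone). RPL14 rose from 373 ± 13.6 to 677 ± 9 CPM. RPLP0 fell from 2763 ± 43.9 to 2137 ± 126 CPM, a call that ended with the neighbourhood subtracted (adjusted p = 0.293; adjusted p from 1.16e-04 to 0.293 over the alternatives). Of 43 mitochondrial ribosomal protein genes, 25 rose and 5 fell, the same adjusted over the list alone. MRPL16 rose from 30.6 ± 0.81 to 60 ± 4.18 CPM and MRPL22 fell from 39.02 ± 1.23 to 25.9 ± 0.927 CPM. Camera called the cytosolic list at adjusted p = 4.7e-06 (adjusted p = 0.608 with an estimated correlation) and the mitochondrial list at adjusted p = 0.00229 (adjusted p = 0.475 with an estimated correlation), with median log2 fold changes of 0.23 and 0.25.

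Of 28 proliferation genes, 12 rose and 9 fell (camera adjusted p = 0.337). The cyclin gene CCNA2 rose from 101 ± 2.02 to 161 ± 3.08 CPM, CDC20 fell from 129.7 ± 5.13 to 87.9 ± 3.74 CPM and MKI67 was not called (456 ± 3.34 to 459.9 ± 62.5 CPM). Of 18 genes of the unfolded protein and integrated stress responses, 5 rose and 11 fell (camera adjusted p = 0.302). The transcription factor gene ATF4 rose from 485 ± 18.8 to 738 ± 24.3 CPM, and the endoplasmic reticulum chaperone genes HSPA5 and HSP90B1 fell from 605 ± 19.7 to 291 ± 15.9 CPM and from 1275 ± 31.9 to 870.4 ± 37.8 CPM. For both lists, the counts adjusted over the list alone were the same.

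Of 14 genes of the interferon response and antigen presentation, 7 rose and 3 fell, the same adjusted over the list alone. HLA-C rose from 19.4 ± 1.295 to 69.3 ± 0.342 CPM and HLA-B from 7.12 ± 1.16 to 41.3 ± 3.904 CPM, both uncertain because genes of this family can share reads. USP18 fell from 35.5 ± 1.34 to 27.2 ± 0.806 CPM. B2M was not called (83.1 ± 2.45 to 78.3 ± 2.04 CPM), but was called higher with the neighbourhood subtracted (log2 0.24, adjusted p = 0.00118; adjusted p from 0.00118 to 0.662 over the alternatives). Camera called the list at adjusted p = 0.0397 (adjusted p = 0.468 with an estimated correlation), and the call ended without Control replicate 3 (adjusted p = 0.0553), without SOX2-KO replicate 1 (0.058), with quantile normalisation (0.0656) and with at least 5 CPM (0.0727; adjusted p from 0.0203 to 0.0727 over the alternatives that keep camera and its preset correlation).

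Over the lists tested, 9 of 33 were called by camera with the preset correlation, all 9 higher and 0 lower, and 0 with the estimated correlation. Camera with the estimated correlation gave 2 of 33 lists at an unadjusted p under 0.05. Among the 9 called lists the estimated correlation ran from −0.035 (interferon) to 0.59 (cytosolic ribosomal proteins). It lay below the preset 0.01 for interferon and for fatty acid synthesis (−0.0033), and above it for the others. For those 2 lists camera's unadjusted p still rose, from 0.0084 to 0.049 and from 0.012 to 0.054. A higher correlation was therefore not the reason there. At an adjusted p under 0.05, fry, which does not compare a list with other genes, called 27, of which 19 were higher and 8 lower.

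Few markers of other cell types were among the genes listed. Of 14 immune cell markers 1 was in the table, below the expression filter, and 0 were tested. Of 11 fibroblast markers 4 were in the table and tested, and of 9 endothelial markers 2. ACTA2 rose from 2.98 ± 0.627 to 4.76 ± 0.365 CPM, FBLN1 fell from 6.68 ± 0.534 to 3.83 ± 0.125 CPM and LUM from 2.96 ± 0.518 to 1.11 ± 0.253 CPM. COL6A3 was not called (1.99 ± 0.681 to 2.54 ± 0.319 CPM). VWF, a gene of endothelial cells and platelets, rose from 3.55 ± 0.562 to 20.5 ± 0.629 CPM (adjusted p = 7.30e-07), and EGFL7 fell from 2.87 ± 0.254 to 1.63 ± 0.546 CPM (adjusted p = 0.016). The EGFL7 call ended without Control replicate 1 (adjusted p = 0.0556), without SOX2-KO replicate 2 (0.0532) and with the neighbourhood subtracted (0.137; adjusted p from 0.00383 to 0.137 over the alternatives). The counts adjusted over the list alone were the same.

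**Figure D2:**
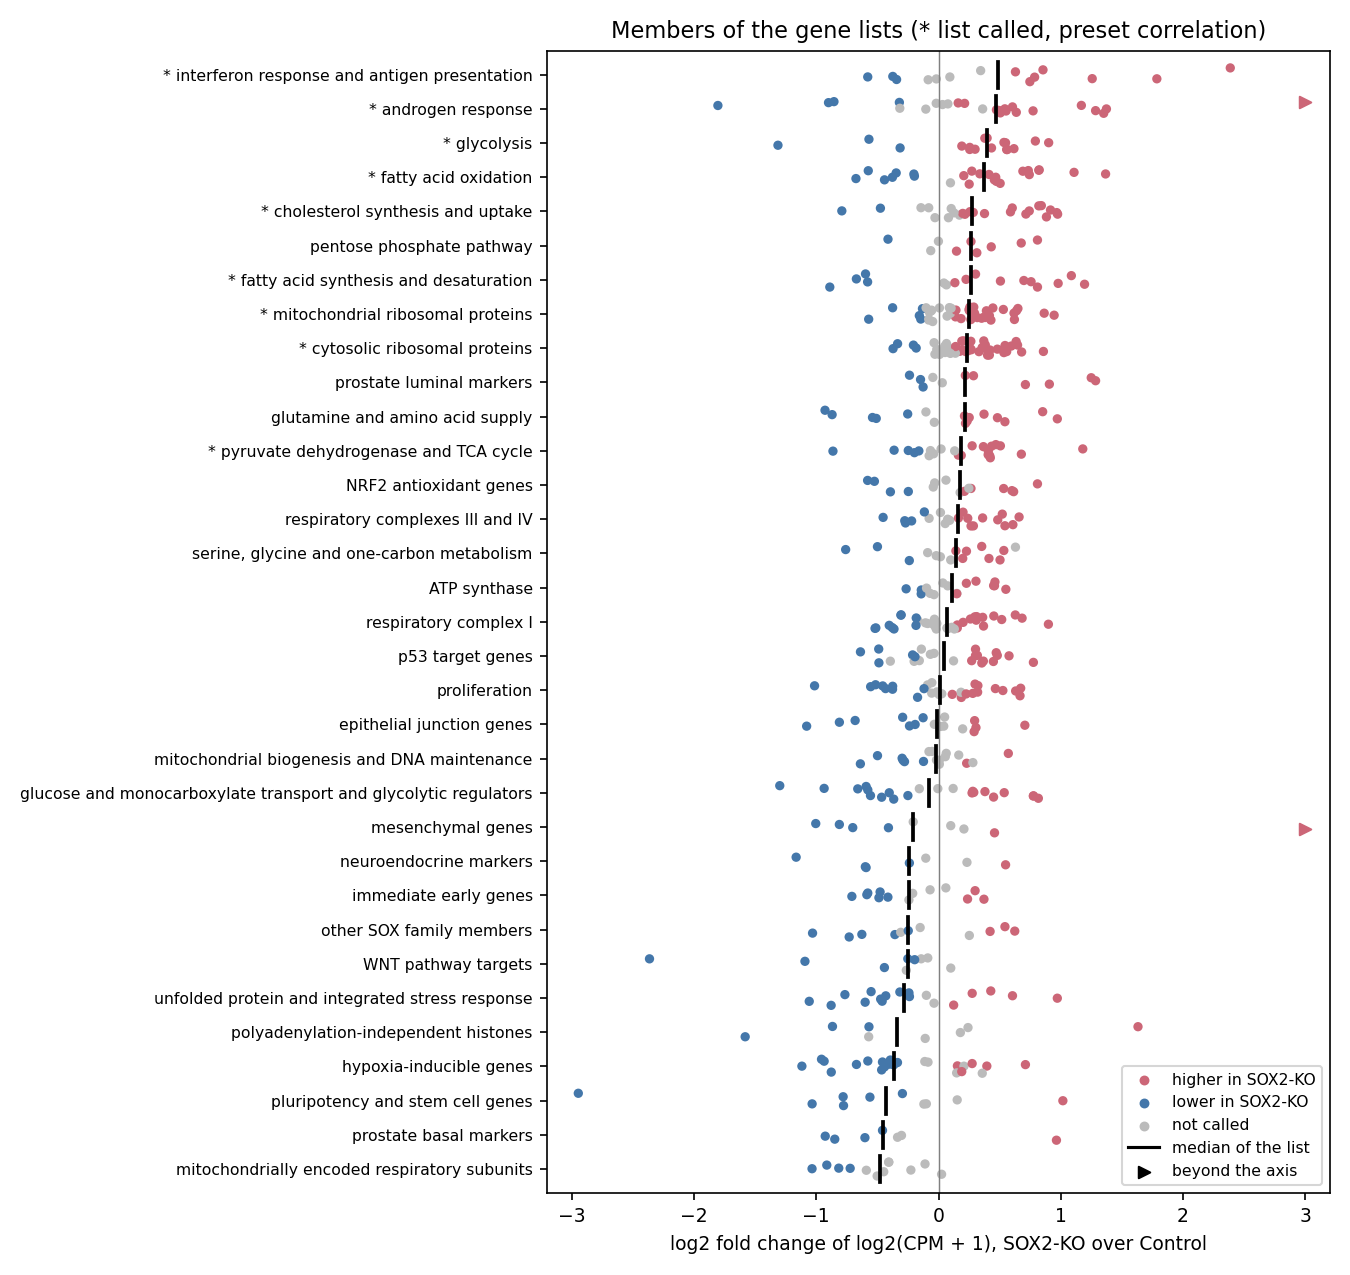
Log2 fold changes of log2(CPM + 1), SOX2-KO over Control, of the members of the 33 lists tested, 1 point per gene, red where called higher, blue where called lower and grey where not called, with a black bar at each list's median and triangles for genes beyond ±3. Glycolysis has a median of 0.40 and hypoxia-inducible genes one of −0.37, and stars mark the 9 lists called with the preset correlation, of which 0 are called with an estimated correlation.

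Fold changes also differed by chromosome, in the same direction in all 3 SOX2-KO libraries on the chromosomes farthest from 0. The median log2 fold change was −0.303 on chromosome 13, −0.298 on 15, −0.256 on 9, −0.249 on 19, −0.235 on 20 and −0.18 on 12, and 0.155 on chromosome 6 and 0.153 on 8. On chromosome 3, the 97 tested genes beyond SOX2 had a median of −0.471, with a 95% bootstrap interval over genes from −0.61 to −0.418, against 0.003 for the 717 genes before it, and 73 of the 97 were called lower and 5 higher. That interval treats neighbouring genes as independent and leaves out the spread between libraries. EPHB3 is 1 of those 97 genes, at positions 184561784 to 184582409. With the chromosomal neighbourhood subtracted, 8599 genes were called, 7302 of them called in the same direction in the main test.

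**Figure D3:**
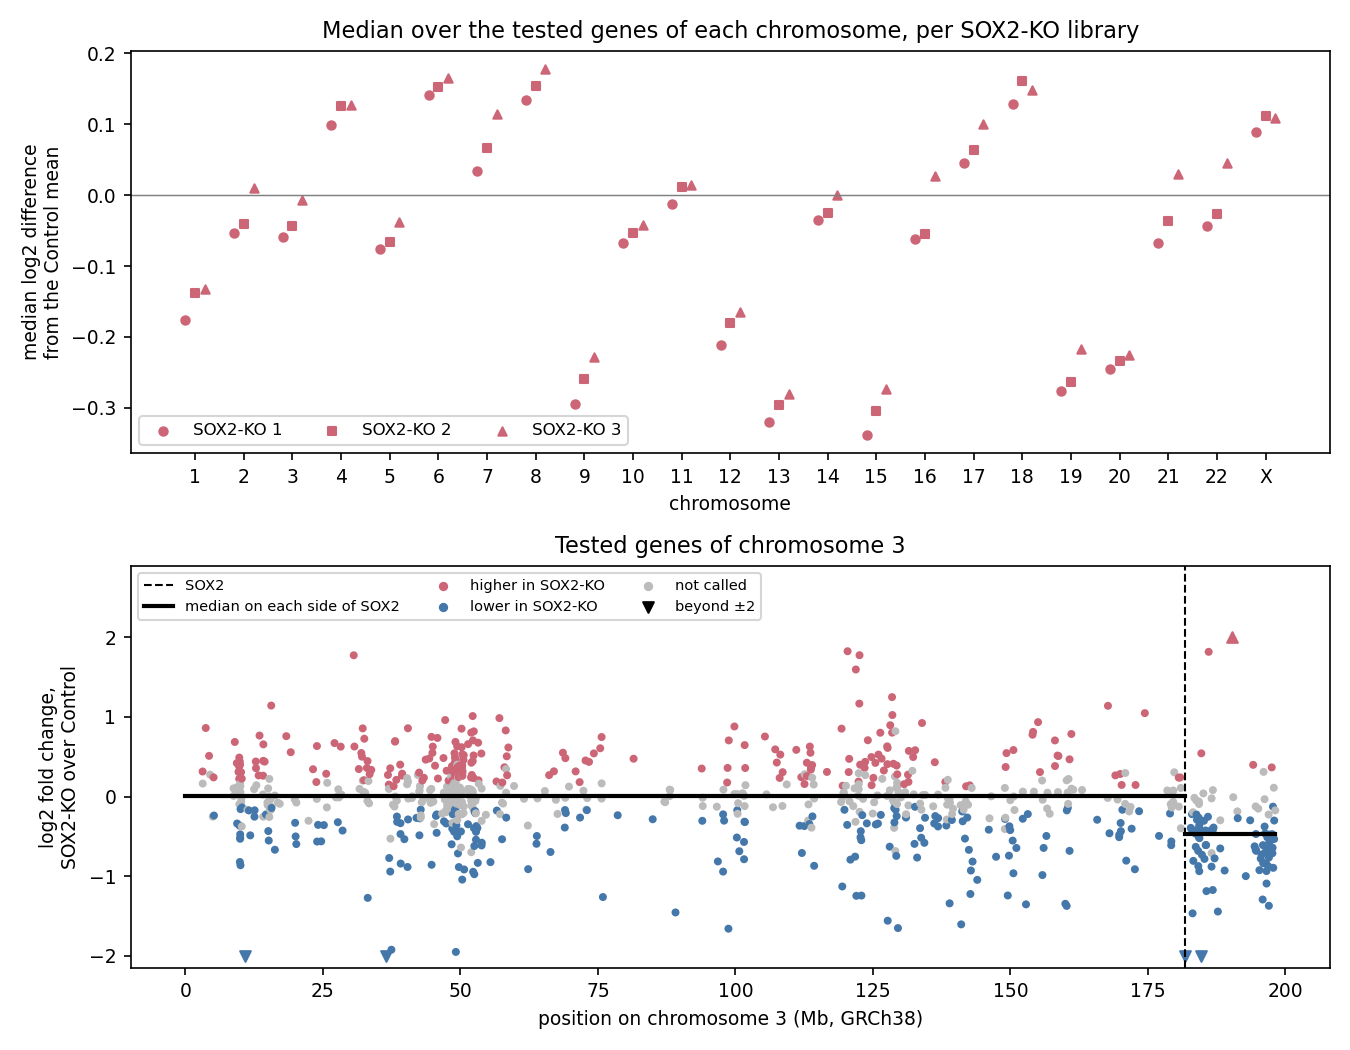
Top, the median over the tested genes of each chromosome of the log2 difference of each SOX2-KO library from the Control mean. Bottom, log2 fold changes of the tested genes of chromosome 3 against position, red where called higher, blue where called lower, grey where not called and triangles beyond ±2, with a dashed line at SOX2 and black bars at the medians, 0.003 before and −0.471 beyond SOX2.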

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

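The alternatives with the chromosomal neighbourhood, limma-voom, GENCODE 29 genes only and the table without mitochondrial and ribosomal RNA genes were chosen after seeing the data. SOX2 was lower under every alternative run, with a log2 fold change from −3.67 to −3.11 (adjusted p from 1.29e-09 to 2.78e-06), and from −3.44 to −3.32 with 1 library left out. The count of 9210 genes ranged from 8083 to 9402 over the other settings, except that a minimum fold of 1.5 gave 1042, by its own construction, and from 8128 to 8889 with 1 library left out. Median-ratio scaling gave 4579 higher and 4522 lower, quantile normalisation 4670 and 4498 and the neighbourhood subtraction 4431 and 4168. The 9 lists called became 0 with the estimated correlation and 27 with fry, which tests each list by itself, and 6 to 11 with 1 library left out.

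The replicate number as a block gave 8727 genes, 7 lists and a log2 fold change of −3.39 for SOX2 (adjusted p = 2.78e-06). The numbers did not pair the libraries: deviations from the group means correlated at −0.045, 0.038 and −0.014 for replicates 1, 2 and 3, and not every library correlated best with its own number.

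Among 200 other named genes, 149 had the same call under every alternative. The values, 3394 with those of the count of lists called, held 27 losses of a call, 54 gains and 10 that turned in sign and were called before or after. The losses and gains include the count of lists called under the estimated correlation and under fry. All 10 turned with the neighbourhood subtracted, since the medians of their neighbourhoods were lower still. The error of those medians is not part of the adjusted p. COX6A1 (log2 0.03), ATP5F1D (0.038) and ATP5F1E (0.133) had been called lower. After the subtraction only ATP5F1E was called higher (limma adjusted p = 0.0292). Its first call also ended with median-ratio scaling (0.126), quantile normalisation (0.0754) and the replicate block (0.0541). The same held without Control replicate 1 (0.0606) or 2 (0.0848) and without SOX2-KO replicate 1 (0.0529) or 2 (0.0656). AHCY (0.13), B2M (0.242), GCLM (0.178), LGR5 (0.136), PCNA (0.245), RPL4 (0.261) and SLC7A1 (0.315) had not been called, with values below 0. Of 624 values for the lists, 26 lost the call, 9 of them with the estimated correlation, and 27 gained one, 16 of them with fry, which is a test of another form. For 2 lists fry called the direction opposite to camera's, which had not called them: mesenchymal genes (adjusted p = 0.000346) and histones (0.0107). The cause of the other changes was not tested.

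The count-based alternatives (edgeR with other size factors, DESeq2 and a count filter) were not run, because the values are CPM, and no comparison made by the authors was in the table. Depth limits statements on genes near the floor of 0.117 to 0.145 CPM.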

Other observations

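The tests of chromosomes, of distal chromosome 3 and of mitochondrial transcripts below, and the splits of the libraries, were chosen after the results had been seen, except those of GC content, gene length and expression level and that of the share of variance in single libraries, while the gene lists and their camera and fry tests were chosen before and the neighbourhood subtraction after. Further gene groups changed in part. Of 9 WNT pathway targets, 0 rose and 5 fell (camera adjusted p = 0.105, median log2 −0.25), among them ASCL2 from 8.68 ± 1.42 to 0.875 ± 0.228 CPM and NKD2 from 5.03 ± 0.699 to 1.82 ± 0.25 CPM. The stem cell receptor gene LGR5 was not called (70.6 ± 0.715 to 66.4 ± 1.66 CPM), but was called higher with the neighbourhood subtracted (log2 0.14, adjusted p = 0.0187; adjusted p from 0.0187 to 0.565 over the alternatives). Of 13 immediate early genes, 3 rose and 6 fell (camera adjusted p = 0.302): MYC rose from 328 ± 17.7 to 387 ± 3.83 CPM and JUNB fell from 41.03 ± 2.27 to 24.7 ± 1.83 CPM. Of 15 NRF2 antioxidant genes, 6 rose and 4 fell (camera adjusted p = 0.302). GCLC rose from 42.3 ± 1.64 to 65.3 ± 2.23 CPM and the thioredoxin reductase gene TXNRD1 fell from 509 ± 16.5 to 387 ± 8.81 CPM, a call that ended with the neighbourhood subtracted (adjusted p = 0.0649; adjusted p from 2.14e-05 to 0.0649 over the alternatives). Of 24 p53 target genes, 11 rose and 5 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.337): XPC, 23.8% of whose exonic bases also lie in a gene of the opposite strand, was called higher, from 72.5 ± 2.99 to 99.4 ± 7.02 CPM. MDM2 and BBC3 fell from 369.6 ± 20.3 to 263 ± 3.48 CPM and from 76.5 ± 7.71 to 48.8 ± 5.12 CPM. Of 16 epithelial junction genes, 4 rose and 7 fell (camera adjusted p = 0.889). The P-cadherin gene CDH3 rose from 18.03 ± 0.937 to 30.1 ± 2.78 CPM and TJP3 fell from 33.7 ± 3.26 to 15.4 ± 1.21 CPM. Of 9 mesenchymal genes, 2 rose, TNC and THBS1, and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.808), among them VIM from 3.59 ± 0.145 to 1.62 ± 0.173 CPM; the median log2 fold change was −0.21 and the mean 0.36, and camera's direction was lower while fry's was higher. Of 8 histone genes without polyadenylation, 1 rose and 3 fell (camera adjusted p = 0.913, direction lower, while fry's was higher): H4C8 rose from 2.69 ± 0.0759 to 10.4 ± 0.396 CPM and H1-5 fell from 7.61 ± 0.82 to 1.95 ± 0.836 CPM, both uncertain because histone genes can share reads. For the lists with no second count, the counts adjusted over the list alone were the same.

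Within the mitochondrially encoded mRNA the balance of transcripts differed between the groups in all libraries. For 11 of 12 transcripts the share of that mRNA did not overlap between the 3 Control and the 3 SOX2-KO libraries. MT-CO1 took 26.15% ± 0.208 in Control and 22.45% ± 0.395 in SOX2-KO (SD, n = 3), MT-ND5 7.57% ± 0.202 in Control and 9.78% ± 0.224 in SOX2-KO, and MT-ND4 16.7% ± 0.202 in Control and 19.1% ± 0.351 in SOX2-KO.

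The 9210 genes of the real grouping compare with at most 1 gene in any of the other splits of the 6 libraries into 3 and 3, and only 1 of the 10 splits, the real one, called as many; with 10 splits a share under 0.05 cannot be reached.

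Blocks of the genome shifted together in SOX2-KO. Chromosomes accounted for 8.51% of the variance of log2 fold changes, against at most 0.38% in 10000 random assignments of genes (permutation p = 0.0001, the smallest these can give). Random assignment breaks every link between neighbouring genes, so this p does not tie the shift to SOX2-KO. Against their own groups, Control replicates 1, 2 and 3 and SOX2-KO replicate 3 also exceeded 0.38% (1.99%, 0.651%, 0.559% and 0.719%). SOX2-KO replicates 1 and 2 did not (0.362% and 0.18%). After a smooth fit on GC content, exon length and expression the share was still 8.39%, which argues against those trends. The limit set beforehand for differences between single libraries, a share under 0.2 of that 8.51%, was not met, since Control replicate 1 against its group reached 1.99%; a second measure, chosen after that, gave an SD over chromosomes of the medians of at most 0.031 within a group, against 0.146 between the groups. Open remain copy number differences between the Control and SOX2-KO cells, a technical difference shared by a whole group and regulation that follows from the loss of SOX2: from the share of 8.51% these cannot be told apart, because each would separate the same libraries.

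The distal end of chromosome 3 was lower as a block. The best single step in fold change along chromosome 3 fell between DNAJC19 and SOX2-OT, 1 tested gene from SOX2 (permutation p = 0.0001, the smallest possible), although resampled genes placed it anywhere from 132.6 to 183.7 Mb. That p compares with genes in random order, so it does not place the step at SOX2. The difference between the genes beyond and before SOX2 was −0.474 and, after the fit on GC content, length and expression, −0.494 (−0.611 to −0.364), and the farther genes beyond SOX2, up to 198.2 Mb, had a median of −0.61 (−0.681 to −0.463) against −0.422 for the nearer ones, so neither those trends nor a local effect fading with distance accounts for it. The intervals in brackets resampled genes, not libraries, and treat neighbouring genes as independent. The median of all genes beyond SOX2 was −0.533, −0.489 and −0.468 in SOX2-KO replicates 1, 2 and 3. In windows of 20 Mb, chromosome 3 was already lower before SOX2, with medians of −0.187 from 140 Mb and −0.091 from 160 Mb. Its earlier windows ran from −0.039 to 0.048. Blocks away from SOX2 also shifted, such as −0.511 for 31 genes of chromosome 13 from 80 Mb and −0.367 for 106 genes of chromosome 15 from 80 Mb. Others rose, such as 0.303 for 55 genes of chromosome 6 from 120 Mb. A candidate explanation is that copies of the chromosome end were lost from a break at SOX2, which DNA copy number would test and these data do not; a block median of −0.471, a ratio of 0.721, is far smaller than the fall of EPHB3 (log2 −5.21, 66.5-fold), which such a loss does not account for.

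The mitochondrial share split the SOX2-KO libraries. In SOX2-KO replicate 3 the transcripts were higher than in replicates 1 and 2 by a mean log2 ratio of 1.00 with an SD over 12 transcripts of 0.111, so the class moved as a whole, as a difference in RNA recovery or in the culture could give. MALAT1, a nuclear RNA, was also higher in replicate 3 (4117 CPM) than in replicates 1 and 2 (2646 and 2459 CPM), against 4557 to 5311 CPM in Control. The share of 2.74% in replicate 3 lies above the Control range of 2.46% to 2.70%, and with 1 such library an effect of SOX2 loss on the amount cannot be told apart from a difference between preparations.

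ZPR1 was listed at 6064 to 17064 CPM, among the highest values of the table; whether these values measure its expression or come from the annotation or the estimation of reads was not tested.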
